A study of Mus musculus with 5 samples.

How the data were processed

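DNase-seq was performed on mouse 3T9 fibroblasts carrying MycER. 3T9 fibroblasts are embryonic fibroblasts immortalised by serial passage, here from embryos of day 13.5 with floxed c-Myc alleles and infected with MycER, per the labels. MycER is a fusion of Myc with the hormone-binding domain of the estrogen receptor, which 4-hydroxytamoxifen (4-OHT) activates. DNase-seq sequences the short fragments released when DNase I cuts chromatin that is not protected by nucleosomes. Per the labels' protocols, nuclei were digested with DNase I, the digests chosen by qPCR for sequencing came from 200 to 300 U/ml, and fragments under 500 bp were gel-selected. The series has 5 samples. The titles give 2 libraries at 0 h (ethanol vehicle), 2 libraries at 4 h of 400 nM 4-OHT, and 1 input of sonicated genomic DNA, for which no peak list was used here. Replicate 2 of each group is the library whose title carries the letter B, and replicate 1 the library without a letter. Nothing in the labels says whether the replicates came from separate cultures, so differences between these libraries may be technical. The 1 permutation p-value given is fixed by the repeated list described in the results and measures no spread between libraries.

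The deposited data were 4 peak lists with a position, a running name and a score for each peak. BWA 0.6.2, SAMtools, MACS 1.4.1 and the build mm9 are named in the submitters' processing notes, without their settings. Whether peaks were called per library is not given in the sources used here, but each list has its own numbering and, apart from the repeated list described in the results, its own intervals, so the lists were treated as called per library. The deposited score of each peak is the caller's own value. MACS writes minus 10 times the log10 of its p-value, a meaning taken here from the caller's name and the values, as no file header states it. The lowest score was 80 in every list after rounding, which on that scale is a p-value of 1e-08, and scores piled up at 3100. How the input entered the calls and whether libraries were brought to equal depth is not given in the sources used here. Read counts were not used here, so the depth behind each peak is unknown and no read-based interval can be given. In a deeper or better digested library a caller of this kind passes weaker sites, so list length and score size were not taken as measures of accessibility between libraries. In the list of EtOH 0 h replicate 1, 1 number of the running peak names has no row.

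Peaks of all lists were merged into sites where they overlapped by at least 1 bp, and a site was called present in a list that had a peak in it. The merge was checked against bedtools 2.31.1. Site scores were the highest peak score of the site in that list. Starts are printed counted from 1, on mm9. The script was tested on 3 simulated lists with 33600 sites in known classes, built with the widths and scores of the vehicle list. By the count of each class, 100% of the simulated sites were recovered. These sites were placed apart with 1 peak in each list that held them, so close neighbours and sites of several peaks were not tested. Computation used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9. For chromosomes 15 and X, the number of missing sites was compared with 10000 random draws in which each site was missing at the rate of its score bin (20 bins) outside the region. Shares of sites carry Wilson 95% binomial intervals. A count of 0 is given with the share that 3 counts would make. The intervals, the shares for 0 and the random draws cover counting error over sites only, and neighbouring sites are not independent.

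Before the data were examined, gained sites were defined as those present in both 4-OHT libraries and in neither vehicle library, and lost sites as the opposite. Concordance was defined as the mean Jaccard index (shared over combined bp) within groups minus that between groups, tested over the 3 splits of the 4 libraries. The alternatives fixed at that time were equal list length (the 35149 highest-scoring peaks of each list), a score of at least 100, a score of at least 100 for presence only, an overlap of 50% of the shorter peak, merging within 500 bp, autosomes only, leaving out each library, the share of overlapping peaks in place of the Jaccard index, and the replicate number as a block. Sites to be named were the 10 gained and 10 lost with the highest lower score of the libraries that hold them, and the 5 shared sites with the highest lowest score, ties in genome order. Because 1 list was deposited under both treatments, gained and lost sites cannot exist under the first definition. The comparison of the remaining 2 lists, the counts under each possible label of the repeated list, and the sites named from them by the same ranking were added after the data had been seen.

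The plan also held promoter positions, 15 gene lists (growth, cell cycle, fibroblast and other cell type genes) and E-box content. These need an mm9 annotation and genome. The gene table used for names was of another build, so these parts, and the cell type markers among the lists, were not analysed here, and sites are given by coordinate without gene names.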

Results

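The study mapped DNase I hypersensitive sites in MycER fibroblasts, to compare accessible chromatin before and after 4 h of Myc activation with 400 nM 4-OHT. Each group had 2 libraries, each described by a list of called peaks. The list of EtOH 0 h replicate 1 held 35149 peaks covering 49.1 Mb, with a median width of 1222 bp. The list of 4-OHT 4 h replicate 2 held 47621 peaks covering 64.4 Mb, with a median width of 1136 bp. The lists of 4-OHT 4 h replicate 1 and EtOH 0 h replicate 2 each held 44956 peaks covering 64.6 Mb, with a median width of 1215 bp. Peaks lay on the 19 autosomes and X in every list, with none on Y, and EtOH 0 h replicate 1 had 1 further peak on the mitochondrial genome. Chromosome X took 1.85% of the peaks of EtOH 0 h replicate 1, 1.62% of those of 4-OHT 4 h replicate 2 and 1.60% of those in each of the other lists.

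The lists of 4-OHT 4 h replicate 1 and EtOH 0 h replicate 2 were the same list. All 44956 intervals and scores were identical, and 10195 lines differed only in how the score was written (with or without decimals). No other pair of lists shared more than 1 identical interval. The 4 deposited lists were therefore 3 distinct lists, 1 of which carries both treatment labels. It is called the ambiguous list below, and the others the vehicle list (EtOH 0 h replicate 1) and the 4-OHT list (4-OHT 4 h replicate 2). Each treatment then has 1 list with an undisputed label, so the comparison of treatments has no replicate check and no p-value is given for it. The title of the vehicle library carries no letter and that of the 4-OHT library carries the letter B. Treatment and replicate letter therefore cannot be told apart where these lists are compared.

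Most accessible sites were found irrespective of the label. The 3 distinct lists merged into 52181 sites, of which 31871 (61.1%) had a peak in every list. These shared sites had higher median scores than sites found in fewer lists, though weak sites were among them too. Their median score was 392 in the vehicle list, 765 in the ambiguous list and 681 in the 4-OHT list, and 13981 of them scored at least 500 in all 3. The caller's score reached at least 3100 in all 3 lists at 2731 sites. Their lowest score was exactly 3100 at every one of them, so the 5 named are the first in genome order. They lie on chromosome 1, at 7078075 to 7079839, 7386752 to 7389042, 13361929 to 13365105, 16093684 to 16096914 and 16646135 to 16648041. At the 29977 shared sites with a single peak in each list, the median width was 1250 bp in the vehicle list, 1402 bp in the ambiguous list and 1346 bp in the 4-OHT list. The peak was wider in the 4-OHT list than in the vehicle list at 68.1% of these sites, and wider in the ambiguous list than in the vehicle list at 74.5%. Median scores at shared sites were also higher in the 4-OHT and ambiguous lists, and depth is unknown. No widening with treatment can therefore be read from these widths.

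Several shared sites were broad called intervals, which were chosen for naming after their widths had been seen. Reads were not used, so they are not shown to be open throughout. The widest lay on chromosome 15 at 76017841 to 76040800 (22960 bp), with 1 peak of 22845 bp in the ambiguous list, 1 peak of 22541 bp in the 4-OHT list and 2 peaks in the vehicle list. The region on chromosome 9 at 102616974 to 102635404 was 1 peak in the ambiguous list, 3 peaks in the 4-OHT list and 4 in the vehicle list. The region on X at 166422313 to 166439695 was 1 peak in the ambiguous list and 3 peaks in each of the other lists. The regions on chromosome 5 at 143571679 to 143586875 and on chromosome 19 at 5838105 to 5850949 were single peaks in all 3 lists. Peak widths at the chromosome 5 region were 14959 bp in the vehicle list and 14723 bp in the 4-OHT list. At the chromosome 19 region they were 12687 bp and 12790 bp. The region on chromosome 2 at 173085861 to 173103002 differed more. There the vehicle list had 6 peaks of 11443 bp together, and the 4-OHT list 2 peaks of 16858 bp together.

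Under the definition of gained and lost sites fixed before the data were examined, 0 sites were gained and 0 were lost with 4-OHT. This follows from the repeated list, since a site cannot be present in it as a treated library and absent from it as a vehicle library. The overlap of libraries within and between groups is bound in the same way. The Jaccard index was 0.684 between the vehicle and ambiguous lists, 0.676 between the vehicle and 4-OHT lists and 0.738 between the ambiguous and 4-OHT lists. With the repeated list in both groups, the mean within groups minus the mean between groups was −0.0638. The split by replicate letter gave the same value, and the other split 0.128. The two-sided exact permutation p over the 3 splits was 1 (smallest possible with 4 distinct lists 0.333). The repeated list forces this p whatever the other lists hold, so it does not bear on treatment. At equal list length the 3 Jaccard indices were 0.727, 0.732 and 0.761.

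Sites present in 1 list of undisputed label and absent from the other lay mostly on the 4-OHT side. The 4-OHT list had 13751 sites with no peak in the vehicle list, 29.6% of its 46415 sites (Wilson 95% interval 29.2% to 30.0%). The vehicle list had 1315 sites with no peak in the 4-OHT list, 3.87% of its 33979 sites (3.67% to 4.08%). When each list was restricted to its 35149 highest-scoring peaks, these counts were 4286 and 3894, a ratio of 1.10 in place of 10.5, and lists of equal length bring the counts close to each other by construction. With a score of at least 100 in both lists the counts were 11828 and 877 (ratio 13.49), and with that score required for presence only they were 9487 and 542 (ratio 17.5). The ambiguous list resembled the 4-OHT list in this respect. It had 11786 sites with no peak in the vehicle list, 26.6% of its 44275 sites, and the vehicle list had 1490 sites with no peak in it. At equal list length these counts were 4381 and 3657.

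**Figure D1:**
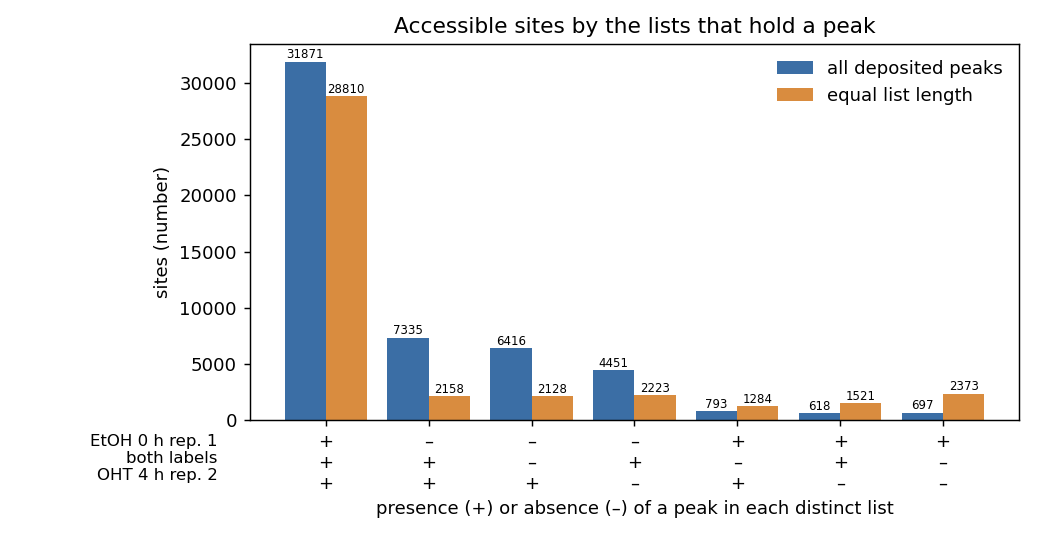
Number of accessible sites (y axis) by the distinct lists that hold a peak in them (x axis, + present and – absent), for all deposited peaks and for the 35149 highest-scoring peaks of each list. The 31871 sites of all lists form the tallest bar, and the 6416 sites of the 4-OHT list alone and 697 of the vehicle list alone become 2128 and 2373 at equal list length.

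The counts were also made under each label the ambiguous list may have. Taken as a 4-OHT library, it left 7335 sites in both 4-OHT lists and not in the vehicle list, and 697 sites in the vehicle list alone. Taken as a vehicle library, it left 6416 sites in the 4-OHT list alone, and 618 in both vehicle lists and not in the 4-OHT list. At equal list length the first pair of counts was 2158 and 2373, and the second was 2128 and 1521. With all peaks the larger count lay on the 4-OHT side under either label. The counts of a pair have unlike criteria. The side with the ambiguous list needs a peak in both its lists, and the other side needs absence from both of these. At equal length the larger count was that of the sites of a list alone under either label (2373 on the vehicle side, 2128 on the 4-OHT side). The direction at equal length thus followed which side held the ambiguous list, and no treatment direction can be read from it.

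Sites that were missing from a list had low scores in the list that held them. The median score was 103 at the sites of the 4-OHT list alone and 91.6 at those of the vehicle list alone, close to the lowest score in the files. At the 7335 sites of the 4-OHT and ambiguous lists that the vehicle list lacked, it was 141 in the 4-OHT list and 136 in the ambiguous list. Of the 4-OHT sites with a score from 80 to 100, 86.9% had no peak in the vehicle list (85.9% to 87.8%). This share was 16.4% from 200 to 500, and 0.241% (0.180% to 0.322%) at 500 and above, or 45 of 18682 sites. The vehicle list followed the same course at lower shares, from 22.6% absent from the 4-OHT list at scores of 80 to 100 to 0.242% from 200 to 500. At scores of 1000 and above, 0 of its 9465 sites were absent from the 4-OHT list, which allows a share of up to 0.0317%. The ambiguous list lacked 63.1% of the 4-OHT sites with scores of 80 to 100, and 5 of the 18682 at 500 and above.

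**Figure D2:**
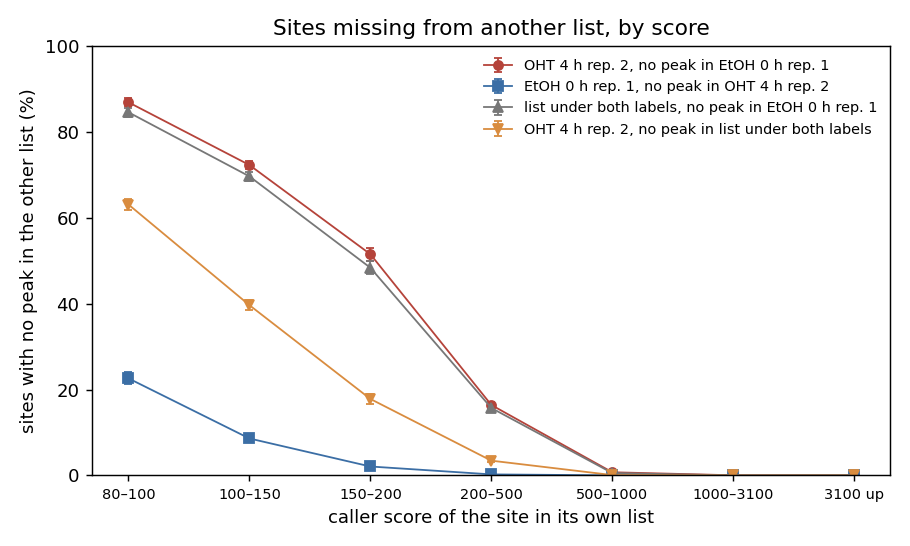
Share of the sites of 1 list that had no peak in another (y axis, %) by the score of the site in its own list (x axis, bins of the caller's score), with Wilson 95% intervals as bars. All 4 comparisons fall to under 1% at scores of 500 and above, and the shares absent from the vehicle list start at 86.9% for the 4-OHT list and 84.6% for the ambiguous list.

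The strongest sites in both lists labelled 4-OHT and not in the vehicle list are named by the ranking fixed beforehand, applied after the repeated list had been found. The first lay on chromosome 18 at 67623849 to 67625537, with scores of 594 in the ambiguous list and 589 in the 4-OHT list. The next were on chromosome 12 at 85749057 to 85750530 (613 and 510 in the same order), chromosome 7 at 89168081 to 89169105 (502 and 481) and chromosome 11 at 98842665 to 98844493 (441 and 604). The others of the first 10 were on chromosome 2 at 26253520 to 26255691, chromosome 5 at 110530800 to 110532906, chromosome 17 at 71146202 to 71147504 and 23801414 to 23805129, chromosome 8 at 129405141 to 129406336 and chromosome 15 at 85909611 to 85910985. Their lower scores ranged down to 417.

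Sites of the 4-OHT list alone were ranked by their score in that list. The strongest lay on chromosome 16 at 94962249 to 94964084 (score 874), and a neighbouring site at 94964954 to 94966208 was also in the 4-OHT list alone (442). Chromosome 14 at 79704462 to 79705925 scored 838, chromosome 2 at 60760972 to 60762339 scored 596, chromosome 1 at 88238591 to 88240866 scored 541 and chromosome 2 at 120867646 to 120868635 scored 509. At no other site did the 4-OHT list score 500 or more without a peak in the ambiguous list.

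Sites of the vehicle list that the 4-OHT list lacked were ranked by their scores in the lists that hold them. These scores cannot be set against those of the 4-OHT list, which were also higher at shared sites (median 681 against 392 in the vehicle list). The strongest in the vehicle list alone was the mitochondrial peak, from position 1 to 6574 (score 862). It was the 1 site of the 14167 with a score of at least 500 in the vehicle list that was absent from the 4-OHT list. The nuclear sites that followed were on chromosome 15 at 87484513 to 87485702 (291), chromosome 1 at 72283542 to 72285088 (222), chromosome 7 at 53268460 to 53269526 (222) and chromosome 16 at 96629037 to 96630207 (214). The other 5 of the first 10 scored between 190.2 and 199.6. Of the sites in the vehicle and ambiguous lists and not in the 4-OHT list, the strongest was on chromosome 7 at 80556367 to 80558049, with scores of 357 and 497. It was followed by chromosome 15 at 38879123 to 38880426 (249 and 341) and chromosome 18 at 53756772 to 53758083 (248 and 346).

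Among the nuclear chromosomes, X had the lowest share of 4-OHT sites missing from the vehicle list, and chromosome 15 the highest share of vehicle sites missing from the 4-OHT list. On X, 151 of 751 sites of the 4-OHT list had no peak in the vehicle list, or 20.1% (17.4% to 23.1%), against 29.8% on the autosomes (29.4% to 30.2%). Scores on X were higher, with 39.8% of the 4-OHT list's sites at 1000 or more against 27.8% elsewhere. On chromosome 15, 127 of 1807 sites of the vehicle list had no peak in the 4-OHT list, or 7.03% (5.94% to 8.30%), against 3.86% over the autosomes (3.66% to 4.08%). Between 70 and 80 Mb of chromosome 15 these were 49 of 445 sites, a window singled out after its counts had been seen. Among the 217 windows of 10 Mb with at least 50 sites, the share missing from the 4-OHT list ranked 3 here. In that comparison chromosome 15 also held the window of rank 1, at 60 to 70 Mb (15 of 113 sites, 13.3%), and that of rank 4, at 10 to 20 Mb (7 of 66 sites, 10.6%). Against the ambiguous list, the window at 70 to 80 Mb ranked 6 (48 of 445 sites) and that at 60 to 70 Mb ranked 3 (14 of 113). Chromosome 19 had the next highest share of vehicle sites missing from the 4-OHT list, 64 of 1177 or 5.44% (4.28% to 6.88%). Against the ambiguous list its share was 6.46% (5.19% to 8.01%), with 4.36% over the autosomes. Chromosome 19 was not set against the number expected from its scores.

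The shares on chromosomes 15 and X were set against the number expected if sites of each score were missing as often as on the rest of the genome. For the vehicle sites missing from the 4-OHT list, 23.6 were expected between 70 and 80 Mb of chromosome 15 (95% of draws 15 to 32), where 49 were observed. On the rest of chromosome 15, 59.0 were expected (45 to 73) and 78 observed. Against the ambiguous list, 48 were observed and 26.5 expected inside the window (18 to 36), and 87 observed and 66.8 expected outside it (53 to 82). Sites of the ambiguous list missing from the 4-OHT list were 336 on chromosome 15 with 305 expected (279 to 331), of which 92 lay in the window with 75.3 expected (62 to 89). On X, 151 sites of the 4-OHT list were missing from the vehicle list and 169 expected (154 to 184), and 126 of the ambiguous list with 143 expected (129 to 157). Vehicle sites of X missing from the ambiguous list were 34, with 20.4 expected (13 to 29), and those missing from the 4-OHT list were 25, with 18.3 expected (11 to 26).

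**Figure D3:**
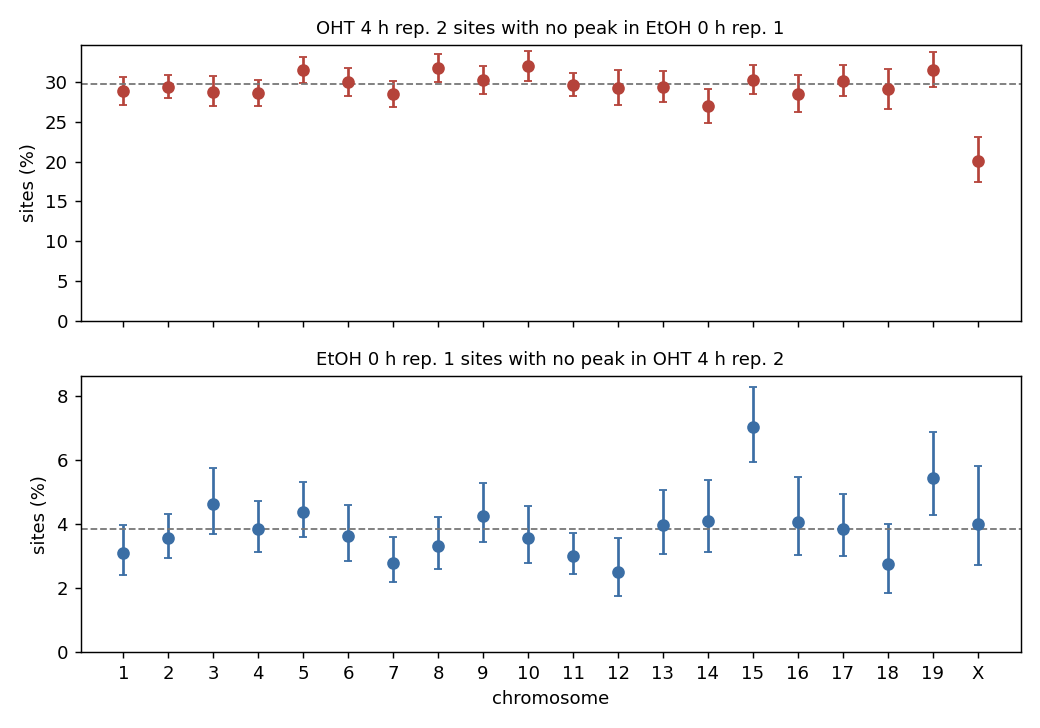
Share of sites with no peak in the other list (y axis, %) on each chromosome (x axis), for the 4-OHT list against the vehicle list (top) and the reverse (bottom). Points are shares, bars are Wilson 95% intervals and dashed lines are the autosomal shares of 29.8% and 3.86%; X lies below the line in the top panel at 20.1% and chromosome 15 above it in the bottom panel at 7.03%.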

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

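The comparison of 1 list per treatment, and all its alternatives, were chosen after the repeated list had been seen. Gained and lost sites were 0 with all 4 lists, with the replicate number as a block and under every alternative that keeps all 4 lists, which the repeated list forces and which says nothing about stability. Leaving out each library in turn gave 0 to 7335 gained sites, the highest without EtOH 0 h replicate 2 and 6416 without 4-OHT 4 h replicate 1. Lost sites ranged from 0 to 697 in the same way, with 618 without 4-OHT 4 h replicate 1. Whether replicate letters pair the libraries cannot be checked, as the repeated list sits in both pairs, and the block left the concordance at −0.0638. Equal list length moved the sites of the 4-OHT list with no peak in the vehicle list from 13751 to 4286, and those of the vehicle list with no peak in the 4-OHT list from 1315 to 3894. For the ambiguous list against the vehicle list the same setting gave 4381 and 3657 in place of 11786 and 1490. The lowest scores kept at that length were 138 in the ambiguous list and 148 in the 4-OHT list, so the change comes from leaving out their weakest peaks. Equal length also draws the counts of each pair together by construction. Requiring a score of 100 for presence alone left 9487 sites on the 4-OHT side and 542 on the vehicle side (ratio 17.5 in place of 10.5), or 630 against the ambiguous list, and a score of 100 in every list left 974 against the ambiguous list. The counts of sites in all lists stayed between 28810 and 39206, within 1.5 times the main count. The concordance lay between −0.0639 and −0.0301, but the repeated list forces its p in every setting, so this range does not bear on treatment. Promoter position, gene lists and E-box content were not run under any setting. Depth is unknown, so a site absent from a list was not detected there and cannot be called closed.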

Other observations

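All tests in this part were chosen after the values had been seen. The list under both labels had sites of its own that neither other list held, 4451 in all with a median score of 102. The sites named in this paragraph were chosen after their values had been seen. The strongest was a region of 9905 bp on chromosome 11 at 3028213 to 3038117 (score 870), next to another at 3026671 to 3028124 (481). Chromosome 7 at 106491956 to 106493738 followed with a score of 505. The 4-OHT list scored 1000 or more at 3 sites with no peak in the vehicle list, each with a peak in the ambiguous list of much lower score. They were chromosome 11 at 6609616 to 6611673 (2057 against 209 in the ambiguous list), chromosome 18 at 6033434 to 6034389 (1898 against 126) and chromosome 7 at 148679650 to 148683926 (1266 against 166).

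The same peaks under opposite treatment labels may come from 1 list entered for 2 libraries. Chance agreement of 2 libraries is argued against by the 44956 identical intervals, when no other pair of lists had more than 1. Which entry is right stays open. At equal list length the ambiguous list was nearer to the 4-OHT list than to the vehicle list, by a Jaccard index of 0.034. With 1 undisputed list per treatment, a shared treatment and a shared sensitivity cannot be told apart. If the ambiguous list is EtOH 0 h replicate 2, it also shares the letter B with the 4-OHT list. A shared replicate letter then cannot be told apart from these either.

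The surplus of sites in the 4-OHT list could reflect lower sensitivity of the vehicle list, through depth or digestion, or sites opened by 4-OHT, and these values do not decide. A difference between the replicate letters cannot be told apart from either. The share of 4-OHT sites with no peak in the vehicle list fell from 86.9% at scores of 80 to 100 to 0.241% at 500 and above. Vehicle sites missing from the 4-OHT list showed such a fall as well, from 22.6% to 0.00706%, where sensitivity of the vehicle list is not in play, and weakly opened sites would also score low. The ambiguous list had 26.6% of its sites absent from the vehicle list. If it is a vehicle library, a share of this size occurs without treatment. If it is a treated library, a treatment effect and a lower sensitivity of the vehicle list could each leave such a share. This value therefore does not decide either.

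The excess of vehicle sites missing from the 4-OHT list on chromosome 15 was not accounted for by low scores when sites were counted as independent. The 49 sites between 70 and 80 Mb were 2.08 times the number expected (5.79 SD, limit 3.74 SD over 276 windows). The rest of the chromosome also lay above the expected range against both lists. The SDs and limits in this paragraph count each site as an independent draw. Neighbouring sites are not independent, so these deviations may be overstated, and those near a limit decide nothing. A candidate explanation is relatively more reads from chromosome 15 in the vehicle library, such as an extra copy in that culture. The 4-OHT sites of chromosome 15 that the vehicle list lacked were 0.905 times the expected count (729 against 805, 4.84 SD). Those of the ambiguous list were 0.922 times (648 against 702.5, 3.50 SD). The limit was 3.42 SD over the 80 combinations of chromosome and list pair, and 3.50 SD lies near it. This limit leaves out the comparisons of the ambiguous and 4-OHT lists. Both counts rest on the same vehicle list, so they are not independent. The candidate leaves the window uncovered, where neither the 4-OHT sites (195, range 188 to 218) nor the ambiguous list's sites (177, range 160 to 190) missing from the vehicle list fell below the expected range. The ambiguous sites of the chromosome missing from the 4-OHT list (336, range 279 to 331) are a comparison without the vehicle library. They lay 2.28 SD above expectation and inside the limit of 3.02 SD over 20 chromosomes. On X, the 4-OHT sites missing from the vehicle list were 0.893 times the expected count (2.40 SD) and those of the ambiguous list 0.881 times (2.44 SD), both inside the limit of 3.02 SD. Vehicle sites of X missing from the ambiguous list were 1.67 times the expected count, and their 3.33 SD lay beyond that limit but inside 3.42 SD. Those missing from the 4-OHT list were 1.37 times the expected count (1.72 SD). These comparisons on X went in the same directions as those of the vehicle list on chromosome 15. Whether the higher scores on X are the whole cause, or the candidate given for chromosome 15 also applies, stays open.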
